A study of Homo sapiens with 6 samples.

How the data were processed

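RNA was measured by RNA sequencing in SU8686 cells, an established human pancreatic ductal adenocarcinoma line, after 72 hr with 20 µM SGC0946 or with DMSO, the solvent control. Each condition had 3 libraries, grouped by their titles, and 6 libraries were analysed. Per the labels' protocols, cells were lysed in Trizol and libraries were made from 1 µg of total RNA with an Illumina TruSeq RNA kit; whether the kit kept the strand is not given in the sources used here. The submitters' processing notes name the human genome build hg38. The aligner, the quantification program and the annotation release are not given in the sources used here.

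The deposited values are FPKM per transcript, computed by the authors, in 1 table for all 6 libraries with 207513 transcripts and 2 decimals. Of these, 199234 had Ensembl names and 8279 had names starting with MSTRG, the form that transcripts assembled from the reads carry; 503 had no gene symbol and stayed out of the gene values. FPKM are already scaled for library size and transcript length, so no count test was used. The deposited FPKM summed to 744466 to 806261 per library, and read counts or depths were not used here. As a hint of depth, values above 0.05 FPKM were taken from single-transcript genes of 500 to 549 bases. The most frequent value was 0.16 to 0.21 FPKM per library, held by 16 to 22 of 159 to 213 genes. It may stand for 1 fragment, which was not checked. No 2 libraries held identical values.

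A gene's value was the sum of the FPKM of its transcripts, over 56571 gene symbols. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. The same test was run per transcript. Fold changes are on the log2(FPKM + 0.5) scale and understate the change of genes with low values. Gene identifiers, positions, GC content and length came from GENCODE release 29 on GRCh38. GENCODE held 198868 of the transcripts, and 98.7% of these had the length the file gives. Positions of genes are those of the annotation.

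Before the data were examined, 45 gene lists with 963 entries were fixed, covering pathways, pancreatic tumour programmes and markers of other cell types; 925 entries matched a symbol as written, 35 matched through another symbol and 3 matched none. The 43 lists with at least 3 tested members were tested with camera from limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes followed a rule fixed at the same time. It took 12 genes with the largest rise and 12 with the largest fall among genes past the threshold with a mean of at least 1 FPKM, an official symbol and no overlap between groups. It also took DOT1L and its complex, up to 4 changed members of each list by size or else 2 members with the highest mean, and DOT1L's transcripts with 3 transcripts per direction whose gene did not pass. Some genes that the rule took are not reported here.

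On data simulated for the same comparison over 15422 genes, the test recovered 64.2% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 95.5% of those changed 3-fold, with 6 false calls. When the GC and length trends of the real libraries were added to the simulated values, false calls rose to 934. Removing the trends with splines of 5 degrees of freedom brought them to 7. The added trends were the fit of those same splines to the real libraries, so this fall was fixed in advance. It cannot show how trends of another form would be removed, or that the real trends are technical. The simulated noise was independent between genes, and its size was taken from the real values after removal of the trends. The recovery and the 6 false calls without added trends therefore need not hold for the main fit, which uses uncorrected values. After the data were seen, this GC and length correction was added, as were fits without the assembled transcripts and fits of the corrected values without each library in turn. Fits without both replicate 1 libraries, KEGG pathways of the deposited annotation, and the difference between the replicate 1 libraries alone were added then too. GC content was known for 99.3% of the tested genes. The correction also set each library's mean deviation from the gene means to 0, so it rescaled the libraries as well. The alternatives fixed beforehand were TPM, median-ratio and quantile scaling, other pseudocounts and filters, limma without a trend or with its robust option, the replicate number as a block, a limit of 1 on the log2 fold change, the most abundant transcript per gene, and each library left out.

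Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.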

Results

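The transcriptome of SU8686 cells, a human pancreatic ductal adenocarcinoma line, was profiled after 72 hr with 20 µM SGC0946 and after DMSO. SGC0946 inhibits DOT1L, the methyltransferase that modifies lysine 79 of histone H3. The comparison asks which transcripts differ between cells with and without the inhibitor. Each condition had 3 libraries, and values below are means ± SD over them in FPKM. Transcripts with a value above 0 numbered 79894 to 83544 in the DMSO libraries and 83618 to 85949 in the SGC0946 libraries. Genes at 1 FPKM or more numbered 13613 to 13799 and 14010 to 14133, and genes above 0 numbered 21466 to 22078 and 22348 to 22601, so the groups did not overlap in these counts. The FPKM sums of the DMSO libraries ranged from 773806 to 806261, above those of the SGC0946 libraries, from 744466 to 750237.

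With SGC0946, 18 of 25 genes of cholesterol synthesis, 10 of 16 of fatty acid synthesis and 14 of 22 NRF2 targets rose, and 16 of 32 interferon-stimulated and 20 of 38 ribosomal protein genes fell. Camera called 14 of the 43 gene lists tested at its preset correlation and 0 with an estimated correlation, where 6 had an unadjusted p under 0.05; fry called 17. Camera called 9 without both replicate 1 libraries. The membrane metalloendopeptidase MME rose from 3.00 ± 0.645 to 16.5 ± 3.09 FPKM, a 5.51-fold change of the means. MME (ENSG00000196549) lies on chromosome 3, from 155024124 to 155183729 in GRCh38. The autophagy receptor SQSTM1 rose from 306 ± 19.5 to 709 ± 5.83, and the stress cytokine GDF15 from 28.0 ± 1.40 to 74.4 ± 5.65. The interferon-induced OASL (ENSG00000135114, chromosome 12, from 121019111 to 121039242) fell from 26.5 ± 0.749 to 7.40 ± 1.47, and the neutrophil chemokine CXCL3 from 80.3 ± 3.33 to 31.5 ± 0.431. In each of these 5 genes, as in every gene that passed limma, the 3 libraries of one group lay outside the range of the other. Each passed the limma test under all alternatives run.

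Of 15537 genes tested with limma, 2164 changed at an adjusted p under 0.05, with 1312 raised and 852 lowered. A 2-fold change was reached by 175 of them, 146 higher and 29 lower. The groups did not overlap in 5915 genes, 38.1% of those tested, where chance gives 10%. The share of raised genes among the changed ones was 60.6%; it was 80.0% with TPM (1727 raised, 432 lowered), 49.2% with median-ratio scaling (1129 raised, 1165 lowered) and 36.6% after the GC and length correction (825 raised, 1428 lowered). In that corrected fit 2253 genes changed, and 1495 of the 2164 were among them in the same direction. The correction also rescaled the libraries, and the median log2 fold change of all tested genes shifted by -0.085, against 0.080 with TPM. How much of the lower share of raised genes came from this rescaling was not tested. Leaving out DMSO replicate 2 gave 257 genes, DMSO replicate 3 gave 220, SGC0946 replicate 2 gave 129 and SGC0946 replicate 3 gave 168, while leaving out DMSO replicate 1 gave 3303; the corrected fit gave 790, 989, 759 and 715 without the first 4 of these. Without both replicate 1 libraries 4026 genes changed (2323 raised, 1703 lowered), 1882 of the 2164 among them in the same direction, and 1772 in the corrected fit; the replicate 1 libraries alone are 1 per group and allow no test. Of the 151 named genes past the threshold, 61 and 54 passed without DMSO replicates 2 and 3, 38 and 47 without SGC0946 replicates 2 and 3, 148 without DMSO replicate 1, 132 without SGC0946 replicate 1 and 140 without both (POLE, TFF3, HLA-DQB1, EZH1, NLRC5, ITGA5, ABCG1, ANO7L1, CDH12P1 and CDH12P3 among those that did not pass), and none turned its direction. With libraries left out the direction was fixed in advance, since the groups did not overlap in any of the 2164 changed genes. After the correction 132 of the 151 named genes passed, and the other 19 follow. The log2 fold change shrank by more than 1.5 times for AFF4 (0.51 to 0.18), ELOVL5 (0.52 to 0.19), CDK1 (0.77 to 0.22), CENPF (0.66 to 0.27), NOP58 (0.57 to 0.29), ATM (0.99 to 0.57), ATR (0.91 to 0.55), NBN (0.74 to 0.23), SKIL (0.83 to 0.33), INHBA (0.33 to 0.05), PHLDA1 (0.33 to 0.03), MDM2 (0.40 to 0.08), CTNNB1 (0.20 to 0.07), ERAP2 (0.60 to 0.28), SNAI2 (0.57 to 0.34), BIRC2 (0.68 to 0.33) and EGFR (0.29 to 0.18). EZH1 (0.45 with a standard error of 0.11 before, 0.40 with 0.11 after) and RPS19 (-0.36 with a standard error of 0.10 before, -0.28 with 0.08 after) shrank less, and their adjusted p went from 0.0449 to 0.0557 and from 0.0493 to 0.0565. Of those that passed, the log2 fold change went from 0.83 to 0.37 for SUZ12, 0.54 to 0.21 for TFRC, 0.96 to 0.52 for SCEL, 0.64 to 0.43 for ANKRD1, 0.55 to 0.35 for EDEM1 and -0.45 to -0.70 for CDH2.

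Genes with AT-rich transcripts were higher with SGC0946. In the decile of genes with the lowest GC content, with a median of 38.6%, 453 genes rose and 6 fell, and the median log2 fold change was 0.47. In the decile with the highest GC content 46 rose and 177 fell, with a median of -0.13. This trend was weak in both replicate 1 libraries, whose Spearman rho of deviation with GC content across genes was -0.02 for DMSO and -0.05 for SGC0946. The other DMSO libraries had 0.51 and 0.44, and the other SGC0946 libraries -0.43 and -0.49; genes are not independent replicates. Between the replicate 1 libraries the lowest decile differed by a median of 0.13 on the log2 scale, and the highest by 0.04.

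**Figure D1:**
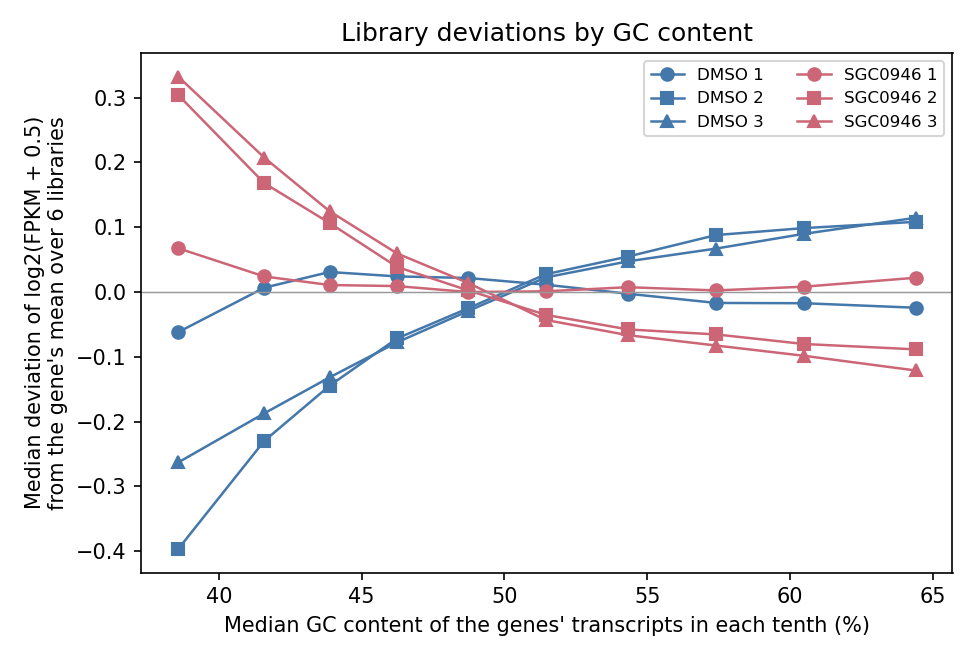
Median deviation of log2(FPKM + 0.5) from each gene's mean over the 6 libraries (vertical axis) in deciles of genes by GC content in percent (horizontal axis), 1 line per library. At the lowest GC content DMSO replicate 2 lay at -0.40 and SGC0946 replicate 3 at 0.33, while DMSO replicate 1 and SGC0946 replicate 1 lay at -0.06 and 0.07.

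DOT1L itself (ENSG00000104885, chromosome 19, from 2164149 to 2232578 in GRCh38) had 7.79 ± 0.699 FPKM with DMSO and 6.41 ± 0.748 with SGC0946. Its log2 fold change was -0.26 with a standard error of 0.12, and it did not pass the limma test (adjusted p = 0.166), but had -0.42 and an adjusted p of 0.0404 without both replicate 1 libraries, where MLLT3 and SKP1 passed too (adjusted p = 0.0291 and 0.0240). Of the 18 tested members of the DOT1L complex and its readers, AFF4, a scaffold of the super elongation complex, rose from 15.6 ± 2.16 to 22.3 ± 1.65 (adjusted p = 0.0315), and the other 17 did not pass (1 raised also adjusted over the list alone). Without DMSO replicate 2 or 3, or SGC0946 replicate 2 or 3, AFF4 had adjusted p values of 0.1003, 0.110, 0.119 and 0.125. It had an adjusted p of 0.0833 after the GC and length correction, which instead lowered NPM1 (adjusted p = 0.00249). KMT2A, the partner in leukaemic fusions, had 17.7 ± 0.161 and 20.7 ± 2.41 FPKM (adjusted p = 0.168), and MLLT3, a reader of acetylated histones, 25.5 ± 2.36 and 28.0 ± 3.95 (adjusted p = 0.496). MEN1 had log2 fold changes of -0.13, CDK9 of -0.03, CCNT1 of 0.07, MLLT1 of -0.09, MLLT6 of -0.10, MLLT10 of 0.01, AFF1 of 0.18, SKP1 of 0.11, ELL of -0.05, ELL2 of 0.27, ELL3 of -0.12, EAF1 of -0.11, EAF2 of 0.22 and NPM1 of -0.02. The list as a whole did not pass the camera test (adjusted p = 0.992).

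The 12 genes with the largest rise under the naming rule included MME, GULP1, an adaptor for the engulfment of apoptotic cells, which rose from 15.7 ± 2.34 to 52.8 ± 6.87, and CST2, a cystatin, which rose from 1.26 ± 0.610 to 4.54 ± 0.168. The aldo-keto reductases AKR1C1 and AKR1C2 rose from 2.31 ± 0.501 to 8.28 ± 1.89 and from 10.8 ± 2.98 to 34.3 ± 6.77; they are near-identical paralogs, so the split between them is uncertain. NMBR, the neuromedin B receptor, was listed at 0 in every DMSO library and at 5.15, 5.72 and 5.57 FPKM with SGC0946, and 99.6% of that came from assembled transcripts. CDH12P1 and CDH12P3, copies with identical values, were listed at 0 in every DMSO library and at 1.81, 4.47 and 0.70 with SGC0946. MICALCL rose from 0.0667 ± 0.0702 to 2.21 ± 1.08 and ANO7L1 from 0.207 ± 0.332 to 1.98 ± 0.907, both low values. The antisense genes IGFL2-AS1 (10.8 ± 5.94 to 61.5 ± 7.61) and FAM222A-AS1 (0.687 ± 0.314 to 3.01 ± 0.372) rose too, with the caveat that without strand their reads cannot be told from those of the opposite gene.

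The 12 genes with the largest fall were led by OASL and by KRT4, a keratin of mucosal epithelium, which fell from 4.06 ± 0.464 to 0.847 ± 0.254. The imprinted RNA H19 fell from 12.6 ± 1.42 to 4.82 ± 0.623, and the acute-phase gene SAA2 from 139 ± 5.40 to 57.2 ± 5.04, in a family of close paralogs. OAS2 fell from 10.0 ± 2.98 to 3.70 ± 0.261, LYPD2 from 13.5 ± 3.14 to 4.55 ± 0.269 and FCGBP, a mucus protein gene, from 61.8 ± 2.51 to 25.8 ± 4.81, of which 63.9% came from assembled transcripts. The mitochondrial cytochrome b gene MT-CYB fell from 515 ± 40.8 to 196 ± 42.8. PLEKHA8P1 (14.4 ± 2.90 to 4.24 ± 1.33) and HIST2H3PS2 (10.3 ± 0.871 to 4.05 ± 2.27) fell as well and are pseudogenes that can share reads with their parents. HOXA-AS2, antisense within the HOXA cluster, fell from 9.55 ± 0.436 to 3.93 ± 0.766, with the same uncertainty of strand.

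**Figure D2:**
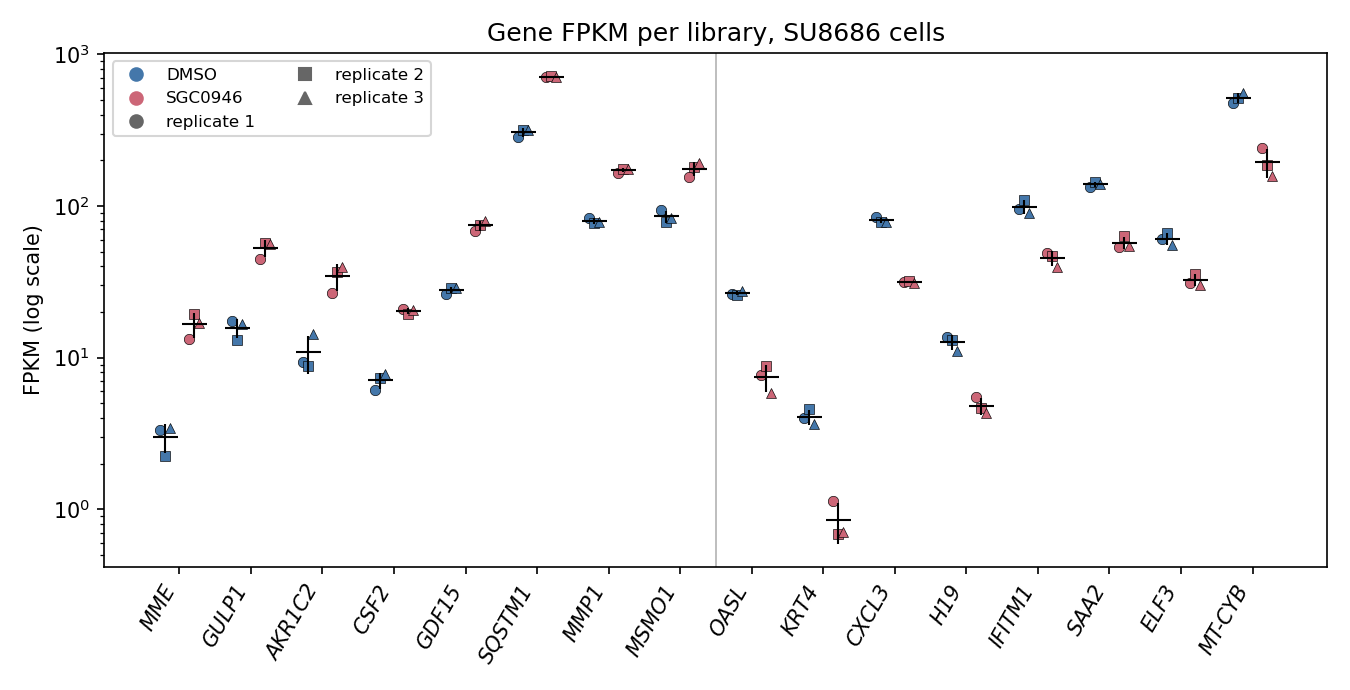
FPKM on a log scale for 8 genes that rose (left) and 8 that fell (right) with SGC0946; each point is 1 library, horizontal bars are group means and vertical lines ± SD (n = 3). MME rose from 3.00 to 16.5 and MT-CYB fell from 515 to 196. The groups did not overlap in any of the 16 genes, as in every gene that passed limma.

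Cholesterol synthesis and uptake genes rose together: 18 of 25 rose and none fell (21 rose adjusted over the list alone). STARD4, a sterol carrier, rose from 12.9 ± 3.17 to 28.9 ± 4.75, the methylsterol oxidase MSMO1 from 85.3 ± 7.93 to 175.9 ± 18.6, SC5D from 36.7 ± 7.04 to 71.0 ± 11.6 and HMGCS1, which makes HMG-CoA, from 99.4 ± 8.99 to 186 ± 20.5. The list median was 0.34 on the log2 scale and also 0.34 after the GC and length correction, where 20 rose. The correction took the log2 fold change from 1.15 to 0.73 for STARD4, 1.04 to 0.62 for MSMO1, 0.95 to 0.51 for SC5D and 0.90 to 0.57 for HMGCS1, and all 4 still passed. Camera gave an adjusted p of 2.24e-10, and adjusted p = 0.301 with an estimated correlation. In fatty acid synthesis 10 of 16 rose and none fell (11 adjusted over the list alone), among them the desaturase SCD from 199 ± 4.21 to 339 ± 19.8, ACSL4 from 10.8 ± 2.05 to 18.1 ± 2.49, ACSS2, which makes acetyl-CoA from acetate, from 58.5 ± 2.25 to 88.1 ± 8.02, and ELOVL5 from 34.6 ± 1.66 to 49.8 ± 1.37. For that list camera gave 1.53e-05 as its adjusted p, and adjusted p = 0.301 with an estimated correlation. The correction left 7 of the 16 raised and took the list median from 0.34 to 0.20, with ACSL4 going from 0.73 to 0.34 and ELOVL5 from 0.52 to 0.19, which then did not pass (adjusted p = 0.125).

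Of 22 tested NRF2 targets, genes of the response to oxidants and electrophiles, 14 rose and none fell (17 adjusted over the list alone). Beside AKR1C1 and AKR1C2, the cystine transporter SLC7A11 rose from 13.5 ± 1.59 to 28.6 ± 3.94 and AKR1C3 from 6.59 ± 0.355 to 13.6 ± 1.41. The list median was 0.40 and camera gave an adjusted p of 1.86e-08, with adjusted p = 0.153 with an estimated correlation. In the corrected fit 13 rose, the list median was 0.33, and SLC7A11 went from 1.05 to 0.44 on the log2 scale. Lysosome and autophagy genes had 8 of 27 raised and 1 lowered (the same numbers adjusted over the list alone), with SQSTM1 joined by GPNMB (0.487 ± 0.371 to 1.93 ± 0.490), WIPI1, an early autophagosome protein (12.1 ± 0.578 to 19.9 ± 1.57), and the cholesterol carrier NPC2 (217 ± 11.1 to 337 ± 4.66). For that list the adjusted p in camera was 0.0184, and adjusted p = 0.301 with an estimated correlation. After the correction it was 6.37e-05, and adjusted p = 0.270 with an estimated correlation. Without the correction it was 0.0800 without DMSO replicate 1, 0.0944 without SGC0946 replicate 1, 0.281 without both and 0.0584 with median-ratio scaling; 51.9% of SQSTM1 came from assembled transcripts.

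Type I interferon-stimulated genes fell: 16 of 32 were lowered and none raised (19 adjusted over the list alone). IFITM1, which restricts virus entry, fell from 98.3 ± 10.4 to 45.1 ± 4.98, in a family of close paralogs, and IFI27 from 70.6 ± 11.8 to 32.7 ± 3.44, beside OASL and OAS2. The list median was -0.43, and -0.63 with 24 lowered after the GC and length correction. Camera gave an adjusted p of 2.24e-10, and adjusted p = 0.301 with an estimated correlation. By contrast, MHC class I presentation genes had 4 of 15 raised and none lowered (5 and 1 adjusted over the list alone), among them B2M, the light chain (2896 ± 301 to 3856 ± 265), HLA-F (93.8 ± 4.21 to 130.2 ± 3.71), NLRC5 (10.1 ± 0.260 to 12.9 ± 0.255) and ERAP2 (11.02 ± 2.02 to 16.8 ± 1.49). Among 9 MHC class II genes HLA-DRA (22.0 ± 0.867 to 27.6 ± 0.775), HLA-DQB1 and HLA-DRB1 rose and none fell (the same numbers adjusted over the list alone). Neither MHC list passed camera (adjusted p = 0.399 and 0.0777), while both did after the correction (adjusted p = 0.0117 and 0.00258), with adjusted p = 0.317 with an estimated correlation for each in the corrected fit. Without 1 library and uncorrected, the adjusted p in camera ranged from 0.228 to 0.742 for class I. For class II it ranged from 0.0161 to 0.249. B2M went from 0.42 to 0.23 on the log2 scale after the correction. These genes have close paralogs.

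Cytosolic ribosomal protein genes fell by small amounts, with 20 of 38 lowered and none raised (32 adjusted over the list alone) and a list median of -0.23. The median was -0.15 with TPM and -0.09 with quantile normalization. RPS2 fell from 5359.5 ± 417 to 3869 ± 224, RPS9 from 1512 ± 169 to 1207 ± 56.1 and RPS19 from 885 ± 66.6 to 690.3 ± 84.5; these genes have many processed pseudogenes. For ribosomal proteins the adjusted p in camera was 1.98e-14, and adjusted p = 0.301 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had 6 of 30 lowered and none raised (12 lowered and 1 raised adjusted over the list alone), including CYC1 (316 ± 22.3 to 248 ± 21.03), SDHA (70.8 ± 3.72 to 56.6 ± 2.13), ATP5B (665 ± 45.0 to 551 ± 15.5) and COX5B (160.1 ± 6.70 to 135 ± 3.16). Camera gave 0.000117 as its adjusted p, and adjusted p = 0.301 with an estimated correlation; with quantile normalization it was 0.0586. After the GC and length correction 13 of them fell (adjusted p = 1.88e-06, and adjusted p = 0.330 with an estimated correlation). The median of this list was -0.15 as computed and -0.07 with TPM.

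Of the 13 mitochondrially encoded genes 5 fell and none rose (6 adjusted over the list alone). With MT-CYB these were MT-CO3 (7318 ± 283 to 4865 ± 157), MT-ATP6 (3511 ± 40.5 to 2693 ± 202), MT-ATP8 (24024 ± 1628 to 17611 ± 2029), which overlaps MT-ATP6, and MT-CO2, with a log2 fold change of -0.26. None of the 7 genes of the NADH dehydrogenase subunits passed, with log2 fold changes from -0.09 to 0.16. After the GC and length correction 8 of the 13 genes fell, with MT-CO1, MT-ND3 and MT-ND4 added (adjusted p = 0.0109, 0.0399 and 0.0477), and MT-ATP8 went from -0.45 to -0.88 on the log2 scale. The list median was -0.09 as computed, -0.33 after the correction, -0.14 with median-ratio scaling, -0.00415 with TPM and at 0 with quantile normalization. Quantile normalization sets genes of the same rank to the same value, so a gene that keeps its rank in all libraries cannot change there. MT-ATP8 lay at 0 in that scaling, while MT-CYB had -1.32 and MT-CO3 -0.51 on the log2 scale. The adjusted p in camera was 0.0151, and adjusted p = 0.578 with an estimated correlation. It was 0.0515 without DMSO replicate 1, 0.138 without SGC0946 replicate 1, 0.272 without both and 0.947 with quantile normalization. After the correction it was 6.37e-05, with adjusted p = 0.330 with an estimated correlation.

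Several pancreatic and epithelial genes fell. Of 14 developmental transcription factors of the pancreas, 4 were lowered and none raised, with or without adjusting over the list alone, among them ELF3 (60.8 ± 5.18 to 32.4 ± 2.94), GATA4 (23.2 ± 2.20 to 13.2 ± 0.728) and FOXA1 (28.3 ± 3.09 to 18.6 ± 0.909). Epithelial genes had 8 of 24 lowered and none raised (10 adjusted over the list alone), among them OVOL1 (4.71 ± 0.384 to 2.99 ± 0.302), the tight junction gene CLDN3 (48.8 ± 4.70 to 32.6 ± 1.53), the desmosome gene PKP3 (134.0 ± 8.57 to 103 ± 7.73) and KRT8 (4057 ± 311 to 3165 ± 143). In the classical tumour programme 4 of 16 fell, PRR15L, TSPAN8, TFF1 and TFF3, and 1 rose (6 and 1 adjusted over the list alone). Camera gave adjusted p values of 0.0213, 0.000481 and 0.0398 for these lists, and adjusted p = 0.301 with an estimated correlation for each. Without DMSO replicate 1 the transcription factor and classical lists had adjusted p values of 0.0800 each, and without SGC0946 replicate 1 of 0.0810 and 0.103, and without both of 0.272 and 0.241. The classical list had an adjusted p of 0.0635 after the GC and length correction, 0.0653 with median-ratio scaling and 0.0586 with quantile normalization. With TPM the list medians were closer to zero change. They were -0.05 for the transcription factors (-0.13 as computed), -0.03 for epithelial genes (-0.11) and -0.13 for the classical programme (-0.24).

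In DNA replication and G1/S, 6 of 30 genes fell, including MCM7 (109 ± 5.06 to 80.2 ± 2.97), MCM2 (86.9 ± 7.09 to 66.8 ± 4.36) and POLE (23.4 ± 1.23 to 18.3 ± 1.60), and the cyclin CCNE2 rose from 4.90 ± 0.361 to 10.4 ± 1.54 (7 and 1 adjusted over the list alone). After the GC and length correction 11 fell and 1 rose, CCNE2, whose log2 fold change went from 1.00 to 0.49. Camera gave an adjusted p of 0.000778, and adjusted p = 0.268 with an estimated correlation. The median of the replication list was -0.18 as computed and -0.09 with TPM. Mitosis genes had 13 of 30 lowered and 3 raised (14 and 7 adjusted over the list alone): KIF20A (54.1 ± 4.07 to 34.9 ± 0.387) and CDC20 (252 ± 15.1 to 169 ± 6.91) fell, while CDK1 (26.5 ± 5.23 to 45.6 ± 8.38) and CENPF (19.3 ± 4.18 to 30.6 ± 3.94) rose. After the GC and length correction 16 mitosis genes fell and none rose, and the adjusted p values of CDK1 and CENPF were 0.140 and 0.116. The list median was -0.07, turned to 0.01 with TPM and was -0.28 after the correction, where camera gave an adjusted p of 4.03e-06, and adjusted p = 0.270 with an estimated correlation. Without the correction camera gave an adjusted p of 0.0103, and adjusted p = 0.555 with an estimated correlation. It was 0.114 without DMSO replicate 1, 0.0810 without SGC0946 replicate 1, 0.449 without both and 0.0971 with quantile normalization. Homologous recombination genes, with AT-rich transcripts (median GC content 42.5%), had 5 of 27 raised and none lowered (8 adjusted over the list alone), among them RAD50, ATM, ATR and NBN, but 1 after the correction (RAD50, from 1.02 to 0.65 on the log2 scale), and the list did not pass camera (adjusted p = 0.130).

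Metastasis-linked proteases and integrins had 7 of 20 raised and 2 lowered (11 and 4 adjusted over the list alone). The collagenase MMP1 rose from 79.7 ± 3.51 to 172 ± 5.65, ITGAV from 17.2 ± 3.82 to 30.3 ± 4.05, the urokinase gene PLAU from 120 ± 6.51 to 167 ± 8.61 and LAMA3 from 72.6 ± 1.36 to 97.8 ± 4.47. Camera gave an adjusted p of 0.0159, with adjusted p = 0.301 with an estimated correlation and 0.0621 after the GC and length correction, where 7 rose and 5 fell; ITGAV went from 0.81 to 0.33 on the log2 scale. Of 30 NF-kB targets and cytokines 8 rose and 5 fell (10 and 5 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.608). CSF2 rose from 7.09 ± 0.863 to 20.2 ± 0.903 and IL1A from 77.0 ± 4.45 to 187 ± 19.4, whereas CXCL3 and SAA2 fell.

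**Figure D3:**
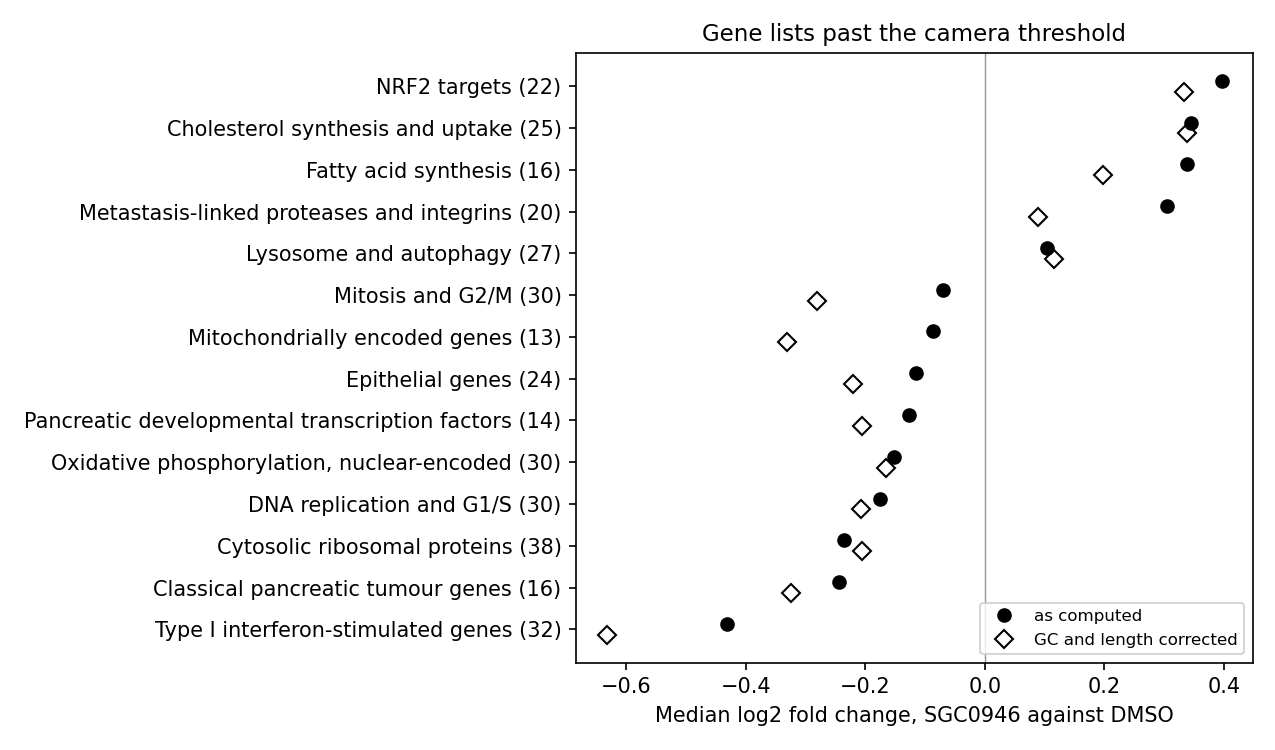
Median log2 fold change of SGC0946 against DMSO (horizontal axis) for the 14 gene lists past the camera threshold, with the number of tested members in brackets; filled circles are values as computed and open diamonds values after the GC and length correction. NRF2 targets lie at 0.40 and 0.33, and type I interferon-stimulated genes at -0.43 and -0.63.

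In the corrected fit 12 of these 14 lists passed camera, proteases and integrins and the classical programme being the exceptions; with an estimated correlation the adjusted p in that fit lay between 0.270 and 0.330. Between the replicate 1 libraries, where the GC trend was weak and no test is possible, the list medians had the same direction as over all 6 libraries. This pair is part of the 6 libraries on which the lists were called. Members past the limma threshold do not overlap between groups, so their direction in the pair was fixed in advance. The agreement, also in the member counts below, is therefore partly built in and is no separate support. The median was 0.42 for cholesterol synthesis (0.34 over all libraries), 0.40 for NRF2 targets (0.40), 0.16 for fatty acid synthesis (0.34), 0.18 for lysosome and autophagy (0.10) and 0.09 for proteases and integrins (0.31, and 0.09 after the correction). In that pair 25 of 25, 20 of 22, 15 of 16, 23 of 27 and 11 of 20 members of these lists were higher with SGC0946. For the lists that fell, the replicate 1 median was -0.69 for interferon-stimulated genes (-0.43 over all libraries), -0.07 for ribosomal proteins (-0.23), -0.07 for oxidative phosphorylation (-0.15) and -0.08 for DNA replication (-0.18). It was -0.26 for mitosis (-0.07), -0.22 for mitochondrially encoded genes (-0.09), -0.13 for epithelial genes (-0.11, and -0.22 after the correction), -0.19 for pancreatic transcription factors (-0.13, and -0.21 after the correction) and -0.26 for the classical programme (-0.24). In the same order, the members that were higher in the replicate 1 pair numbered 0 of 32, 2 of 38, 5 of 30, 9 of 30, 6 of 30, 1 of 13, 8 of 24, 3 of 14 and 6 of 16.

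Of 22 p53 targets 3 rose and none fell (8 and 1 adjusted over the list alone): GDF15, the CDK inhibitor CDKN1A (28.9 ± 3.02 to 57.2 ± 2.90) and MDM2 (13.03 ± 0.784 to 17.3 ± 0.443). Of 31 ATF4 stress genes 6 rose and 2 fell (6 and 3 adjusted over the list alone), among them ALDH1L2, CHAC1, DDIT3 (20.7 ± 1.05 to 35.4 ± 2.44) and SLC7A11. Xenobiotic metabolism had 5 of 13 raised and none lowered (6 and 1 adjusted over the list alone), with CYP3A5 (3.57 ± 0.432 to 7.86 ± 1.48), ABCG2, CYP1A1 and CYP1B1. TGF-beta targets had 5 of 18 raised and none lowered (5 and 1 adjusted over the list alone), with SKIL, BHLHE40 and INHBA among them. Mesenchymal genes had 5 of 17 raised, LOX, SNAI2 and ITGA5 among them, and 2 lowered, including CDH2 (6 and 3 adjusted over the list alone). Of 22 endoplasmic reticulum chaperones and stress genes 6 fell, CRELD2, XBP1 and HYOU1 among them, and EDEM1 rose (6 and 3 adjusted over the list alone). MYC and ribosome biogenesis had 2 of 24 raised, NOP58 and TFRC, and 5 lowered, BOP1 and ODC1 among them (2 and 7 adjusted over the list alone). Chromatin regulators had 2 of 32 raised, SUZ12 and EZH1, and 4 lowered (3 and 7 adjusted over the list alone), of which ARID1A, a subunit of the SWI/SNF remodeller, fell from 49.9 ± 3.23 to 29.7 ± 0.676 and HDAC1 from 168 ± 8.501 to 132 ± 4.71. These lists did not pass camera, with adjusted p from 0.0594 for xenobiotic metabolism to 0.678 for ATF4 stress genes; xenobiotic metabolism, chromatin regulators and endoplasmic reticulum stress did after the GC and length correction (0.0126, 0.0397 and 0.0397). In the corrected fit they had adjusted p = 0.272, 0.270 and 0.535 with an estimated correlation. Without 1 library and uncorrected, the adjusted p in camera ranged from 0.0362 to 0.131 for MYC and ribosome biogenesis. For xenobiotic metabolism it ranged from 0.0455 to 0.108. The correction changed the counts of TGF-beta targets to 3 raised and 2 lowered, of MYC and ribosome biogenesis to 1 and 8 and of chromatin regulators to 1 and 6.

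Basal-like tumour genes had 3 of 22 raised (FGFBP1 and SCEL among them) and 4 lowered (KRT17 and VGLL1 among them), the same numbers adjusted over the list alone. Mucins and trefoil factors had 2 of 11 raised (MUC13 and MUC20) and 3 lowered (MUC1 and TFF1 among them), and these too had the same numbers adjusted over the list alone. RAS-MAPK genes had 3 of 22 raised (DUSP5, PHLDA1 and IER3) and 1 lowered, ETV4 (3 and 3 adjusted over the list alone), with an adjusted p of 0.314 in camera and 0.0491 after the GC and length correction, where it had adjusted p = 0.330 with an estimated correlation. Glycolysis and hypoxia had 2 of 29 raised (ENO2 and VEGFA) and 3 lowered, TPI1 and GAPDH among them (5 and 6 adjusted over the list alone). YAP and TEAD targets had 1 of 22 raised, ANKRD1, and 2 lowered, IGFBP3 (359 ± 15.6 to 222 ± 2.12) and AJUBA (1 and 2 adjusted over the list alone). Apoptosis regulators had 1 of 21 raised, BIRC2, and 2 lowered, BIK and CFLAR (3 and 2 adjusted over the list alone). EGFR and its ligands had 1 of 11 raised, EGFR, and 1 lowered, TGFA (2 and 1 adjusted over the list alone). CDK inhibitors and cyclin D had CDKN1A and CDKN1C raised and CDKN2C lowered of 7 (3 and 2 adjusted over the list alone). LXR targets had 2 of 7 raised, APOE (39.5 ± 2.67 to 68.8 ± 0.452) and ABCG1, and none lowered (2 adjusted over the list alone). The list of WNT and beta-catenin targets had 1 of 12 raised (none adjusted over the list alone). This was CTNNB1, which encodes beta-catenin itself, so no target proper was raised. These lists did not pass camera, with adjusted p from 0.130 for mucins to 0.971 for EGFR. For mucins it ranged from 0.0455 to 0.210 without 1 library. The correction changed the counts of glycolysis and hypoxia to 4 raised and 6 lowered, of YAP and TEAD targets to 1 and 4, of EGFR and its ligands to 0 and 3, of RAS-MAPK genes to 3 and 2, of apoptosis regulators to 0 and 2 and of WNT targets to 0 and 0.

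No member of the 14 tested HOX-A genes and cofactors passed limma, over all genes or adjusted over the list alone: HOXA10 had 12.1 ± 1.18 and 11.02 ± 0.342 FPKM and HOXA3 10.5 ± 2.16 and 8.94 ± 2.71. None of 12 replication-dependent histone genes passed either way, with HIST1H2BK at 24.6 ± 2.87 and 22.1 ± 2.73 and HIST2H4A at 13.7 ± 6.34 and 11.1 ± 2.32. The median, the mean and the camera direction did not all have the same sign for endoplasmic reticulum stress, basal-like genes, glycolysis, apoptosis, CDK inhibitors, LXR targets, EGFR, endothelial markers and the DOT1L complex. List medians changed sign under another scaling for ATF4 stress genes, apoptosis, basal-like genes, LXR targets, the DOT1L complex, EGFR, endoplasmic reticulum stress, glycolysis, HOX-A, YAP targets, p53 targets and endothelial, fibroblast and hepatocyte markers.

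Markers of other cell types gave few tested genes. Of 4 fibroblast markers THY1 rose (23.4 ± 2.87 to 35.2 ± 0.406) and TAGLN fell (53.4 ± 5.85 to 34.8 ± 4.77), of 4 endothelial markers ESAM fell (23.1 ± 1.55 to 17.3 ± 1.04), and of 5 hepatocyte markers SERPINA1 rose (6.82 ± 0.296 to 11.5 ± 0.0611), each also adjusted over the list alone. Among 4 leukocyte markers CD68 had 24.1 ± 0.0764 and 25.5 ± 1.84 FPKM and CD14 1.36 ± 0.440 and 1.14 ± 0.531, and none passed, with or without adjusting over the list alone. In camera the adjusted p was 0.976 for fibroblast, 0.749 for endothelial, 0.656 for hepatocyte and 0.824 for leukocyte markers. Only 2 acinar markers, PRSS1 and PRSS2, and 1 endocrine marker, ISL1, could be tested, so those lists were not tested as lists.

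At the level of transcripts, 174 of 50370 changed, 112 raised and 62 lowered. Of these 154 belonged to genes that changed and 20 to genes that did not. A transcript of HDDC2 was listed at 0 in each DMSO library and at 2.98, 4.78 and 6.76 FPKM with SGC0946. Assembled transcripts of RABGGTA (21.8, 5.52 and 5.28 with SGC0946) and KRT80 (7.88, 8.27 and 3.41) were likewise listed at 0 with DMSO. Transcripts of PIGB (3.06, 2.40 and 1.82 with DMSO) and C15orf40 (2.08, 3.11 and 1.92) were listed at 0 with SGC0946, and one of PAM16 fell from 8.35 ± 1.28 to 2.66 ± 0.313. The gene sums of these 6 did not pass. The DOT1L transcript ENST00000398665 had 6.86 ± 0.305 and 5.61 ± 0.517 FPKM (adjusted p = 0.307). After the GC and length correction 389 of 44089 transcripts changed. Without DMSO replicates 1, 2 and 3 in turn limma called 45, 10 and 0 transcripts and without SGC0946 replicates 1, 2 and 3 it called 18, 4 and 0, where 6511 (DMSO replicate 3) and 6159 (SGC0946 replicate 3) had an unadjusted p under 0.05. Without both replicate 1 libraries it called 0, with 10034 at an unadjusted p under 0.05.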

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

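The GC and length correction, alone or with the replicate block, the fit without assembled transcripts, the fits without both replicate 1 libraries and the corrected fits without each library were chosen after the results were seen; the other tests here were planned. Of the 151 named genes past the threshold, none turned its direction under any alternative. With libraries left out, the block, or another pseudocount, filter or limma option this was fixed in advance. The groups did not overlap in any gene past the threshold. Of the 151, 141 stayed past it with TPM, 146 with median-ratio scaling, 136 with quantile normalization and 132 after the GC and length correction. It was 145 of 150 without assembled transcripts and 121 of 150 with the most abundant transcript per gene. Past it stayed 85 without a filter, 101 in limma without a trend and 140 without both replicate 1 libraries. In no scaling did the median log2 fold change of all genes shift by more than 0.1. Depth limits low genes, where 1 fragment may be worth 0.16 to 0.21 FPKM in short single-transcript genes. The cause of the changes below was not tested unless stated.

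The count of changed genes was 689 without a filter (401 raised, 288 lowered), where 27898 genes share the adjustment, and 1056 in limma without a trend (782 raised, 274 lowered). With a limit of 1 on the log2 fold change it was 175 (146 raised, 29 lowered). With TPM 432 genes were lowered, and with the most abundant transcript 561. After the GC and length correction 825 were raised and 1428 lowered. Without 1 library the count ranged from 129 to 3303 (89 to 1997 raised, 40 to 1306 lowered), and after the correction from 715 to 2159. The count of transcripts was 46 without a filter, 482 at a mean of at least 2 FPKM, 30 without a trend, 84 with the fold limit, 389 after the correction and 0 to 45 without 1 library; the 0 came from limma without DMSO replicate 3 and without SGC0946 replicate 3, with 6511 and 6159 at an unadjusted p under 0.05. DOT1L stayed between -0.35 and -0.22 on the log2 scale without 1 library. Without both replicate 1 libraries 4026 genes changed (2323 raised, 1703 lowered) and 1772 after the correction, and limma called 0 transcripts, with 10034 at an unadjusted p under 0.05; DOT1L had -0.42 and passed (adjusted p = 0.0404).

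Deviations from the group mean correlated at -0.14, -0.08 and -0.10 between libraries with the same number. No SGC0946 library correlated best with its own number. This check gave no sign that the replicate numbers pair the libraries, but it cannot exclude pairing. A shared batch that weakens opposite trends in both groups, as the GC trend is weak in both replicate 1 libraries, would give negative correlations. With the replicate number as a block, 69 genes changed (47 raised, 22 lowered), and 417 (210 raised, 207 lowered) with the block and the GC and length correction; no transcript passed in limma with the block, with 6311 at an unadjusted p under 0.05. Of the 151 named genes, 31 stayed past the threshold with the block and 72 with block and correction. The block leaves fewer residual degrees of freedom.

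Of 43 lists, 14 passed camera, 9 to 16 without 1 library, 15 to 20 after the correction without 1 library, 17 in fry and 0 in camera with an estimated correlation, where 6 had an unadjusted p under 0.05. The adjusted p with an estimated correlation was 0.153 for NRF2 targets, 0.268 for DNA replication, 0.555 for mitosis, 0.578 for mitochondrially encoded genes and 0.301 for the other 10. In fry it was 0.0628 for mitochondrially encoded genes and 0.0521 for mitosis. Classical tumour genes had 0.0653 with median-ratio scaling, 0.0586 with quantile normalization, 0.0990 without a filter, 0.0597 with the most abundant transcript, 0.0635 after the correction and 0.0637 with block and correction. Lysosome and autophagy had 0.0584 with median-ratio scaling. With quantile normalization mitochondrially encoded genes had 0.947, mitosis 0.0971 and oxidative phosphorylation 0.0586. A gene that keeps its rank in all libraries cannot change with that scaling, which limits the value for the mitochondrially encoded genes. Proteases and integrins had 0.0621 after the correction and 0.0770 with block and correction. Without 1 library the adjusted p ranged from 0.0161 to 0.103 for classical genes, 0.00656 to 0.0944 for lysosome, 0.00223 to 0.138 for mitochondrially encoded genes, 0.00121 to 0.114 for mitosis and 0.0108 to 0.0810 for pancreatic transcription factors. Without both replicate 1 libraries 9 lists passed, 16 after the correction, and it was 0.241 for classical genes, 0.281 for lysosome, 0.272 for mitochondrially encoded genes and for pancreatic transcription factors and 0.449 for mitosis.

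Directions turned in 88 cases, 39 for 13 genes and 49 for 13 lists, none past the threshold in either fit. The log2 fold changes with TPM were 0.051 for CDK9, 0.027 for ELL and 0.060 for NPM1. With median-ratio scaling MLLT10 had -0.037; with quantile normalization CCNT1 had -0.080, MLLT10 -0.092 and NPM1 0.14. With the most abundant transcript EAF1 had 0.053, MEN1 0.17 and MLLT10 -0.82. After the correction, with or without the block, CCNT1 had -0.24, CDK9 0.0049, EAF2 -0.0995, ELL2 -0.0022, MLLT10 -0.054, MLLT3 -0.091 and SKP1 -0.045. Without 1 library the range was -0.044 to 0.18 for CCNT1, -0.13 to 0.033 for CDK9, -0.10 to 0.014 for ELL, -0.24 to 0.046 for ELL3, -0.53 to 0.12 for HIST2H4A, -0.22 to 0.13 for MLLT10 and -0.069 to 0.054 for NPM1. ELL3 had 0.091 and NPM1 0.11 without both replicate 1 libraries.

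The adjusted p of lists that turned was, in fry, 0.715 for basal-like genes, 0.114 for CDK inhibitors, 0.558 for the DOT1L complex, 0.655 for EGFR and 0.429 for glycolysis. With TPM it was 0.885 for the DOT1L complex, 0.932 for EGFR and 0.951 for fibroblast markers. With quantile normalization it was 0.947 for apoptosis, CDK inhibitors and EGFR, 0.994 for endoplasmic reticulum stress and 0.430 for glycolysis. Without a filter it was 0.937 for the DOT1L complex, 0.914 for endothelial and 0.944 for hepatocyte markers, and at a mean of at least 2 FPKM 0.952 for the DOT1L complex and 0.959 for fibroblast markers. With the replicate block it was 0.985 for the DOT1L complex and fibroblast markers. With the most abundant transcript it was 0.886 for CDK inhibitors and 0.823 for the DOT1L complex, EGFR and fibroblast markers. After the correction it was 0.881 for basal-like genes and 0.664 for CDK inhibitors and glycolysis, and with block and correction 0.848, 0.678 and 0.521. Without assembled transcripts it was 0.955 for the DOT1L complex. Without both replicate 1 libraries it was 0.690 for ATF4 stress genes, 0.747 for LXR targets, 0.735 for the DOT1L complex and EGFR and 0.960 for fibroblast markers. Without 1 library it ranged from 0.686 to 0.992 for apoptosis, 0.326 to 0.878 for ATF4 stress genes, 0.707 to 0.948 for LXR targets, 0.777 to 0.977 for the DOT1L complex, 0.791 to 0.992 for EGFR, 0.764 to 0.992 for fibroblast markers, 0.414 to 0.975 for glycolysis and 0.586 to 0.977 for leukocyte markers.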

Other observations

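The KEGG pathways, the tests of GC content and of an effect of SGC0946 on AT-rich genes, the tests of GC content and scaling for interferon-stimulated and mitochondrial genes, and the comparisons of counts of genes, transcripts and lists with other splits of the libraries were chosen after the results were seen. Both hypotheses on H3K79 methylation use the corrected values, so they too came after the correction was chosen.

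Among 320 KEGG pathways with 10 to 300 tested protein-coding genes, camera called 14, all of them also after the GC and length correction, which called 39 in all. Genes of the KEGG spliceosome were lower, with 18 of 135 lowered and 6 raised (adjusted p = 0.0202), and so were those of the proteasome, with 6 of 45 lowered and 1 raised (adjusted p = 0.0140). Hematopoietic cell lineage had 14 of 51 raised and none lowered (adjusted p = 0.00179), rheumatoid arthritis, a set of cytokine, vacuolar ATPase and MHC class II genes, had 20 of 65 raised and 2 lowered (adjusted p = 0.00410), and graft-versus-host disease, a set of MHC and cytotoxicity genes, had 7 of 19 raised and none lowered (adjusted p = 0.00162). Collecting duct acid secretion, largely vacuolar ATPase subunits, had 9 of 20 raised and none lowered (adjusted p = 0.0141), mineral absorption 10 of 34 (adjusted p = 0.0276) and steroid hormone biosynthesis, which holds AKR1C genes, 8 of 21 (adjusted p = 0.0276). For each of these pathways the call was lost, at adjusted p = 0.782 with an estimated correlation.

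Genes with AT-rich transcripts were higher with SGC0946. Transcript length was argued against as the cause, since genes of the lowest GC decile shorter than the median gene had a median log2 fold change of 0.36. The Spearman rho of the trend with GC content spanned 0.532 over the DMSO libraries and 0.442 over the SGC0946 libraries, and the group means differed by 0.631, so library preparation and an effect of SGC0946 cannot be told apart. An exact permutation test of the trends, 3 libraries against 3, gave p = 0.1, the smallest it can give. Both replicate 1 libraries showed almost no trend and may be a separate batch, which the labels do not say; with 1 library per group such a batch allows no test of its own.

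Type I interferon-stimulated genes were lower with SGC0946. GC trends are argued against as the whole cause, since the list median was -0.63 after their removal. Scaling is argued against too, since the highest list median was -0.35 under the other scalings. With 1 library left out the highest was -0.35, without SGC0946 replicate 1, and it was -0.36 without DMSO replicate 1. The 16 lowered members did not overlap between groups, so only the size of this median, and hardly its direction, was open. The replicate 1 libraries, which deviated most in their groups, were not left out together in this test. As a hypothesis found on the same data, SGC0946 may lower basal interferon signalling in these cells, and interferon signalling itself was not tested. A change in cell density or in secreted interferon was not tested.

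MT-CYB and 4 other mitochondrial genes were lower with SGC0946. Reads moving to nuclear copies are argued against: 134 copies changed by -0.622% of the FPKM that the 5 genes lost, so they did not gain. Scaling is argued against as the whole cause, since 5 genes stayed lowered with TPM and with median-ratio scaling. With quantile normalization 3 did, but a gene that keeps its rank cannot change there. GC trends ran the other way: the median GC content of the mitochondrial list was 44.3%, and AT-rich genes were higher with SGC0946. Removing the trends took the list median from -0.09 to -0.33. That 5 of 5 genes stayed lowered after the correction was therefore largely fixed in advance. As a hypothesis, SGC0946 may lower these 5 transcripts; whether the NADH dehydrogenase genes differ from them stays open, since 2 of those 7 also fell after the correction. How the authors' program divided reads between overlapping mitochondrial transcripts was not tested.

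DOT1L's mark, H3K79 methylation, is known to follow transcription, so as a hypothesis its inhibition might lower highly expressed genes most. The Spearman rho across genes of the corrected log2 fold change with mean expression was -0.229. A rho of -0.1 or less, and lower than in every other split, was the limit written before this test. That limit was on corrected values, and the correction was added after the data were seen, so the test was not planned beforehand. Another of the 10 splits of the libraries reached 0.214 in size, so the margin is narrow, and 10 splits are too few for a share under 0.05. The second hypothesis, that genes with a long genomic span fall most because the mark lies over gene bodies, was not borne out: rho was 0.0713, against 0.0665 at most in the other splits. Genes are not independent replicates in either test. H3K79 methylation was not measured in these libraries. The SGC0946 libraries also had more detected genes and lower FPKM sums, and whether these differences give the slope with expression was not tested.

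With 10 splits of the 6 libraries, the real one included, a share under 0.05 cannot be reached, and in each case the real split was the 1 with the highest count. It gave 2164 changed genes against at most 2 in another split, 2253 against 2 after the GC and length correction, and 174 transcripts against 6. For gene lists it gave 14 against 8, and 18 against 8 after the correction, so camera at a preset correlation also called lists where libraries of both groups were mixed. Every other split has libraries of both conditions on each side. A difference between the conditions then widens the spread within the sides and lowers the counts of genes and transcripts. The other splits therefore do not measure the false calls of the real split.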
